A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

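Deletion strains of the budding yeast Saccharomyces cerevisiae were grown as 1 pool, and the abundance of each strain was read from DNA tags on a 2-colour array. Per the labels, the pool held 5896 heterozygous diploid knockout strains that were sporulated, and haploid MATa cells were then selected at 30 °C on a medium (magic medium) on which only such haploids grow. The selection was run with or without benomyl, a drug that binds tubulin and breaks down microtubules. Each strain carries short DNA barcodes, its uptag and downtag, which were amplified from genomic DNA of the pool, labelled and hybridised to a TagArray. Per the labels, the pool without drug was labelled with Cy5 and the pool with drug with Cy3, and both pools of an array had the same number of days of selection. On the no-drug array both dyes carried a pool without drug.

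There were 10 arrays, 1 for each of the benomyl doses 0, 1, 5, 10, 15, 20, 25, 30, 35 and 40 µg/ml. Selection lasted 2 days at 0 to 10 µg/ml, 3 days at 15 µg/ml and 4 days at 20 to 40 µg/ml, so days and dose rise together. No dose had a replicate array, and the p-values below measure the scatter of single arrays about a fitted line or about a group mean. Nothing in the labels says which arrays came from separate sporulations.

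The deposited values are log2 ratios per spot. Per the labels, images were taken with a GenePix 4000B scanner and read with the GenePix 5.1 program. Which dye is the numerator, and whether the authors normalised the ratios, is not given in the sources used here. With Cy5 as numerator, the default of that program, the ratio is the pool without drug over the pool with drug, and a positive log2 ratio means fewer cells of the strain in the drug pool. This direction is called likely here. Its basis is the dyes in the labels. The lists fixed beforehand do not settle it, since the tubulin cofactor, prefoldin and spindle checkpoint lists had positive medians, at 4.55, 3.95 and 3.08, and the dynein list a negative one, at -1.10. The microtubule motor list had a median of -0.63 and was not called, so it weighs on neither side. Were the ratio the other way round, every sign below would turn. The median of the deposited log2 values over named spots lay between -0.0801 and 0.189 per array. On 9 arrays the ratios were whole hundredths, which makes 0.01 the lowest ratio and about -6.8 the lowest log2 value after centring. On the 10 µg/ml array only 4.27% of ratios were whole hundredths, so that array was handled in another way before it was deposited. A fall that reaches this floor is understated, and spots near it are also missing more often. Of 115 named spots at a ratio of 0.02 or lower at 35 µg/ml, 6.96% had no value at 40 µg/ml, against 0.171% of the other 18679.

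The value table has 22575 spots, of which 2539 hold no value on any array. The platform annotation names 18794 spots, each to 1 gene, and 5325 genes in all. Symbols were updated through the gene number for 5321 of these, and 4 kept the older name. Another 1242 spots have values and no name. A gene has 2 spots in 4439 cases, 4 or 6 in 93 cases and 12 or 14 in 793 cases. The annotation does not mark uptags and downtags. Spots of a gene lie 10971 positions apart in 2 sections of the layout. Repeated spots within a section correlated at 0.65 to 0.97 across strains, while the sections correlated from -0.05 on the no-drug array to 0.67 at 35 µg/ml, so each section was taken to hold a different tag.

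Each array was centred on its median over named spots, and all spots of a strain were averaged. Strains with values on at least 8 arrays were kept, which were all 5325, of which 5322 had values on every array. There were 18 values coded as a ratio of 1000000, and these were set to missing, a choice made after the values were seen. The dose trend was a straight line against dose per strain, fitted over the 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom and 3.34 prior degrees of freedom). Its size is the fitted log2 change from 0 to 40 µg/ml with its standard error. The second comparison set the mean of the 5 arrays of 4 days against that of the 4 arrays of 2 days in limma, and left out the 3-day array. P-values were adjusted by Benjamini and Hochberg over all strains, with 0.05 as the threshold. As a measure with no test, strains at least 2-fold above or below the array median were counted on each array.

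Before the data were examined, 21 gene lists with 398 genes were fixed, of which 384 were on the array. The lists covered microtubule and chromosome functions, drug efflux, chromatin and transcription, ribosomes, amino acid synthesis, actin and, as a background, genes whose haploid deletion does not grow. They were tested with limma's camera at a preset correlation of 0.01 between strains, and with an estimated correlation and with fry as alternatives. Members past the threshold were counted with p-values adjusted over all strains and, separately, adjusted over the list alone. The strains named were fixed by a rule: the 15 largest rises and 8 largest falls past the threshold, up to 4 members of each list with the largest test statistic, every member of lists of 8 or fewer, and up to 8 strains in each direction that passed only the second comparison. Any strain outside that rule is said to be chosen after its values were seen.

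The fits were tested on simulated data for 5325 strains with 200 changed. The simulated dose trend recovered 14.9% of changes of 1 on the log2 scale, 64.2% of changes of 2 and 95.5% of changes of 4, with 7 wrong calls among 123. The simulated comparison of days recovered 26.9%, 77.6% and 97.0% at the same sizes, with 4 wrong calls among 138. The simulated noise was normal, independent between arrays and of 1 size per strain. The real spread across strains grew from 0.51 without drug to 1.46 at 40 µg/ml, so these rates may not hold for the real arrays. Alternatives covered centring, scaling, quantile normalization, the summary of spots, missing values, the dose scale, days as a covariate, subsets of arrays, robust and weighted fits, a limit on extreme ratios, the set test and leaving out each array. Fits on uptags or downtags alone were planned and could not be run because tags are not marked, and the 2 sections of the layout were used instead, as chosen after the data were seen. A reference gene table gave gene names and chromosomal neighbours, and no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python.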

Results

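Tags of 5325 deletion strains of yeast were read on 10 tag arrays, 1 at each benomyl dose from 0 to 40 µg/ml, in pools selected for haploids. Some of these genes are needed for haploid growth, and for them the signal need not come from a haploid strain. Benomyl depolymerises microtubules. Each value is a log2 ratio of tag signals, likely the pool without drug over the pool with drug, and it is relative to the median strain of its array. A strain whose ratio rose with dose then became scarcer in the drug pool relative to the pool without drug, compared with the median strain. A strain whose ratio fell became relatively more abundant there. The ratio does not show which pool changed, since the pool without drug was also selected for more days at higher doses. All signs would turn if the ratio ran the other way. No dose was repeated, and the number of arrays limits the precision.

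The first question is how far the pool was altered at each dose. On the no-drug array, 129 strains lay at least 2-fold above and 204 at least 2-fold below the median, which is 6.25% of strains and the level of this measure with no drug in either pool. At 1 µg/ml the counts were 208 and 189, or 7.46%. They were 335 and 643 at 5 µg/ml, 286 and 678 at 10 µg/ml, 229 and 397 at 15 µg/ml and 304 and 378 at 20 µg/ml. From 25 to 40 µg/ml they went from 567 and 526 to 1026 and 966, and 37.4% of strains were at least 2-fold off at 40 µg/ml. Among 81 genes whose haploid deletion does not grow, which stand for background signal, 8 were above and 11 below by 2-fold without drug, 11 and 8 at 1 µg/ml, 6 and 16 at 5 µg/ml, 6 and 23 at 10 µg/ml, 2 and 12 at 15 µg/ml, 3 and 3 at 20 µg/ml, and 3 and 14 at 40 µg/ml, so this background was largest at 10 µg/ml. From 0 to 15 µg/ml a larger share of these genes than of all strains was off, and at 20 and 40 µg/ml a smaller share. The 6.25% is thus too low as a noise level for such genes. The standard deviation across strains was 0.51 on the log2 scale without drug and 1.46 at 40 µg/ml. With arrays scaled to equal spread, the counts were 408 and 667 without drug and 337 and 351 at 40 µg/ml, so the growth of these counts is a growth of the spread of the ratios. No test applies to single arrays.

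**Figure D1:**
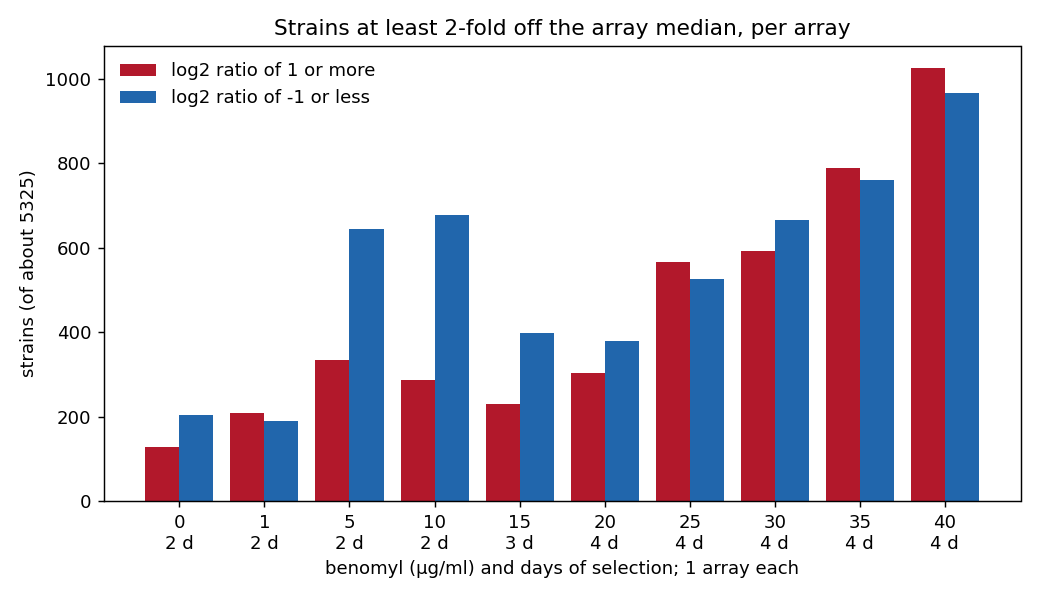
Bars give the number of strains at least 2-fold above (red) or below (blue) the median of each array, by benomyl dose in µg/ml and days of selection, with 1 array per dose and no error bars. Counts go from 129 and 204 without drug to 1026 and 966 at 40 µg/ml, and the bars below the median are the taller ones at 0, 5, 10, 15, 20 and 30 µg/ml.

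The main comparison asked which strains changed with dose. The strains with the largest rises lacked MAD2 (YJL030W), a spindle checkpoint protein, with a fitted log2 change from 0 to 40 µg/ml of 6.67 ± 0.86 (SE, n = 10 arrays), and CIN4 (YMR138W), a small GTPase of the tubulin folding pathway, with 6.62 ± 0.98. They were followed by IRA1 (YBR140C), a negative regulator of Ras, at 6.47 ± 1.64, the polyubiquitin gene UBI4 at 6.45 ± 0.94 and WHI2, a regulator of the stress response, at 6.36 ± 1.09. Among the 8 largest falls were SNF2 (YOR290C), SNF5 (YBR289W) and SWI1 (YPL016W), subunits of the SWI/SNF chromatin remodeller, at -8.11 ± 1.13, -7.43 ± 0.83 and -7.22 ± 1.24. SWI1 had no value at 40 µg/ml, so its line was fitted to 9 arrays. Ratios of all 8 strains reached the floor of the measure on 2 to 4 arrays, so their falls are understated and their rank is not certain. A fitted change may also exceed the ratio reached. IRA1 was at 6.78, 6.77 and 6.52 at 25, 30 and 35 µg/ml and at only 2.67 at 40 µg/ml, and its call was lost without the 35 µg/ml array, at 5.83.

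In all, 547 strains rose and 486 fell in limma at an adjusted p below the threshold, and 1000 and 775 had an unadjusted p below it. The fitted change was over 4-fold in 264 and 256 of them. The rest of the 15 largest rises were of PSO2 at 6.11 ± 0.73, DHH1 at 5.87 ± 0.82, NFU1 at 5.80 ± 0.64, NPR3 at 5.43 ± 0.54, AAT2 at 5.18 ± 0.83, CIN1 at 5.14 ± 1.62, EAP1 at 4.94 ± 0.52, MAD1 at 4.91 ± 0.41, and HTZ1 and SWR1, both at 4.88. At 40 µg/ml DHH1 and AAT2 were at 4.34 and 3.76, below their fitted changes. PSO2 repairs DNA crosslinks, DHH1 is an RNA helicase of mRNA decay, NFU1 acts in iron-sulfur cluster assembly, NPR3 inhibits TORC1, AAT2 is an aspartate aminotransferase and EAP1 binds the cap-binding protein eIF4E. The others of the 8 largest falls were TIM12 at -7.32 ± 0.94, LST4 at -7.21 ± 1.03, TRM44 at -7.15 ± 1.40, LEU4 at -6.85 ± 0.83 and SLM4 at -6.69 ± 0.65. LST4 and SLM4 act in amino acid signalling to TORC1, TRM44 modifies tRNA and LEU4 makes a leucine precursor. TIM12 encodes a subunit of a mitochondrial import complex that is needed for growth, so a haploid strain without it is not thought to exist.

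The counts depend on how the spread of the arrays is treated. They were 41 and 24 with arrays scaled to equal spread, 107 and 133 after quantile normalization and 851 and 379 on ratios as deposited, where the median change of all strains was 0.33 in place of 0.09. The share of calls that rose was 53.0%, 63.1% with equal spread and 69.2% as deposited. All 65 strains called with equal spread were also called in the same direction without that scaling. Leaving out the 40 µg/ml array gave 314 and 308, and leaving out the 1 µg/ml array gave 372 and 321. With days as a covariate 157 rose and 182 fell, among the 4-day arrays alone 93 and 157, and among the 2-day arrays alone 0 in limma, where 199 and 320 had an unadjusted p below the threshold. Of the 88 named strains called, 33 kept the call with days as a covariate, 29 on the 4-day arrays and 49 with log2(dose + 1).

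Most strains lacking the tubulin isotype TUB3 or a tubulin folding cofactor rose. Of 7 measured, 5 rose (6 with p adjusted over the list alone), and none fell, with a median change of 4.55 (camera adjusted p = 0.00224, and adjusted p = 0.0558 with an estimated correlation). With days as a covariate the list was not called, at 2.58 (adjusted p = 0.578). The list median was -0.23 at 5 µg/ml and 2.43 at 10 µg/ml, and only some members were high at low dose. CIN1, a cofactor, was at 2.02 on the log2 scale at 1 µg/ml and 6.52 at 5 µg/ml, then between 6.71 and 8.51. TUB3 was at 1.32 at 1 µg/ml, 4.36 at 5 µg/ml and 6.06 at 10 µg/ml, and its fitted change was 4.55 ± 1.30. CIN4 was at -0.23 at 5 µg/ml and 4.46 at 15 µg/ml. ALF1 rose by 4.63 ± 1.20 after a dip to -2.73 at 5 µg/ml, with a ratio of 2.50 at 40 µg/ml, and RBL2, which binds beta-tubulin, rose by 2.79 ± 0.51 with its largest value, 3.23, at 40 µg/ml. CIN2 followed the course of CIN1, at 6.01 at 5 µg/ml, and did not pass the threshold with a line (4.21 ± 1.60, limma adjusted p = 0.089). PAC2 was at -0.09 ± 0.61.

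Strains of the prefoldin (GIM) complex, which hands tubulin and actin chains to the chaperonin, were above the median at low dose. Of 6 measured, 3 rose (5 with p adjusted over the list alone), with a median change of 3.95 (camera adjusted p = 0.00214, and adjusted p = 0.394 with an estimated correlation). GIM4, PAC10 and YKE2 rose by 4.72 ± 0.91, 3.99 ± 0.84 and 3.91 ± 0.88. The 2 sections of the layout differed for GIM4, at 8.54 and 0.91, and had opposite signs for GIM3, at -1.07 and 4.14. PFD1, GIM5 and GIM3 had fitted changes of 4.14 ± 1.41, 3.55 ± 1.25 and 1.53 ± 0.70, not past the threshold. The list median was 0.96 at 1 µg/ml, 2.76 at 5 µg/ml and 4.24 at 10 µg/ml, and it lay between 3.86 and 5.30 above that. Among the 4-day arrays alone the median slope, scaled to 40 µg/ml, was -0.30 for these strains and -0.29 for the tubulin cofactor list, with no call. With equal spread the prefoldin list was at 1.26 and was not called either (adjusted p = 0.425), nor with days as a covariate, at 3.44 (adjusted p = 0.181). The calls of CIN1 and TUB3 were lost without the no-drug array, at 3.22 and 3.08, and without several other single arrays, and that of ALF1 without the 35 µg/ml array, at 4.74.

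**Figure D2:**
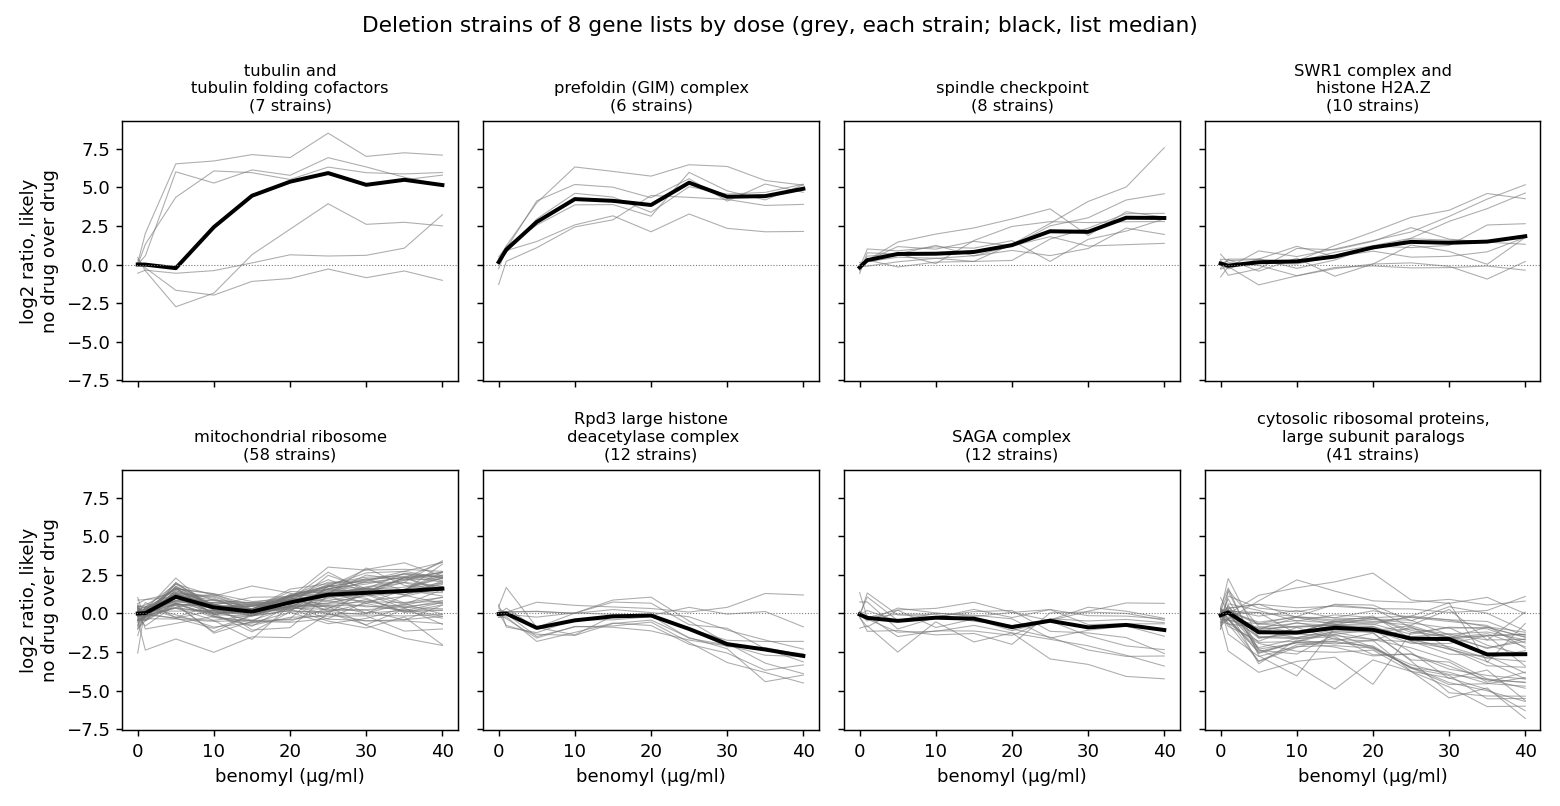
Lines give the log2 ratio of each strain (grey) and the median (black) of 8 gene lists against benomyl in µg/ml, with 1 array per dose. The prefoldin median reaches 4.24 at 10 µg/ml, the spindle checkpoint median goes from 1.26 at 20 µg/ml to 3.02 at 40 µg/ml, and the median of large-subunit ribosomal proteins ends at -2.65.

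Spindle checkpoint strains rose at higher doses. Of 8 measured, 7 rose (8 with p adjusted over the list alone), with a median change of 3.08 (camera adjusted p = 2.86e-06, and adjusted p = 0.0175 with an estimated correlation). MAD2 and MAD1 (4.91 ± 0.41) were at 0.41 and 0.40 at 10 µg/ml and at 7.57 and 4.59 at 40 µg/ml. BFA1, of the spindle position branch, rose by 3.58 ± 0.51, the kinase BUB1 by 3.24 ± 0.49 and SGO1, which guards centromeric cohesion and tension sensing, by 2.92 ± 0.64. MAD3 and BUB2 rose by 1.93 ± 0.54 and 1.70 ± 0.49, and BUB3 had a change of 1.15 ± 0.42 that did not pass over all strains. The SGO1, MAD3 and BUB2 rises came mostly from 1 section of the layout, at 4.94, 3.57 and 3.53 there against 0.92, 0.29 and -0.12 in the other. The calls of MAD3 and BUB2 were lost without the no-drug, the 35 or the 40 µg/ml array, at 1.43 and 1.65 without the last.

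Of 13 strains of the CTF19 kinetochore complex, 5 rose (7 with p adjusted over the list alone) and none fell, with a median of 0.99 (camera adjusted p = 0.00358, and adjusted p = 0.291 with an estimated correlation). MCM16 and CTF19 rose by 2.40 ± 0.55 and 2.21 ± 0.47, and both lost their calls without the 40 µg/ml array, at 1.52 and 1.68. CTF3 rose by 1.70 ± 0.42. In the list of sister chromatid cohesion and fork factors, the 3 subunits of the alternative clamp loader rose, namely DCC1 by 2.70 ± 0.60, CTF8 by 1.74 ± 0.46 and CTF18 by 1.72 ± 0.46, and no other of the 10 passed over all strains (4 with p adjusted over the list alone). CTF8 and CTF18 lost their calls without the 40 µg/ml array, at 1.05 and 1.47, and also without the 35 µg/ml array, and CTF8 without the 1 µg/ml array. This list was not called (adjusted p = 0.993). Its median was -0.51 and its mean 0.33.

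Microtubule motor and plus-end strains went both ways. BIK1, a plus-end protein, rose by 3.51 ± 0.40 and the bundling protein ASE1 by 1.92 ± 0.41, while KAR3, a minus-end motor, and its partner CIK1 fell, with changes of -1.63 ± 0.35 and -1.73 ± 0.46. Of 11, 2 rose and 3 fell, the list was not called (adjusted p = 0.696), and with p adjusted over the list alone 3 rose and 3 fell. The ASE1 call was lost without the 40 µg/ml array, at 1.53, and that of CIK1 without the no-drug or the 1 µg/ml array, at -1.47 and -1.40. Of 11 dynein and dynactin strains, 4 fell (8 with p adjusted over the list alone) and none rose, with a median of -1.10 (camera adjusted p = 0.00181, and adjusted p = 0.397 with an estimated correlation). Against log2(dose + 1) the list was not called, at -0.75 (adjusted p = 0.0787). DYN2, DYN3, NDL1 and ARP1 fell, with changes of -1.46 ± 0.39, -1.44 ± 0.45, -1.43 ± 0.40 and -1.37 ± 0.34. The calls of DYN2, DYN3 and NDL1 were lost without the 40 µg/ml array, at -0.97, -0.79 and -0.76, and also without the 35 µg/ml array, that of DYN3 without 7 of the 10 single arrays in all, and that of ARP1 without the 35 µg/ml array, at -1.10.

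Chromatin complexes moved in opposite directions. Strains of the SWR1 complex, which places the histone variant H2A.Z, rose: of 10, 6 rose (7 with p adjusted over the list alone), with a median of 2.18 (camera adjusted p = 1.22e-05, and adjusted p = 0.0324 with an estimated correlation). SWR1 itself, HTZ1, which encodes H2A.Z, ARP6 and VPS71 rose by 4.88 ± 0.39, 4.88 ± 0.45, 4.48 ± 0.42 and 2.28 ± 0.27. Strains of the large Rpd3 histone deacetylase complex fell: 10 of 12 fell, with a median of -2.53 (camera adjusted p = 2.20e-06, and adjusted p = 0.181 with an estimated correlation). With p adjusted over the list alone, 10 fell and 1 rose. SDS3, PHO23, SAP30 and RXT3 fell, with changes of -4.21 ± 0.61, -3.01 ± 0.57, -2.85 ± 0.49 and -2.16 ± 0.37. Of 12 strains of the SAGA coactivator, 6 fell (7 with p adjusted over the list alone), with a median of -1.55 (camera adjusted p = 0.00153, and adjusted p = 0.0430 with an estimated correlation). SGF73, SGF29, SPT8 and SPT3 fell, with changes of -3.28 ± 0.62, -3.07 ± 0.34, -2.81 ± 0.37 and -2.69 ± 0.51. In the PAF1 and H2B ubiquitination list, RTF1 fell by 1.74 ± 0.52 and CDC73 rose by 1.46 ± 0.45, the other 5 did not pass, and the list was not called (adjusted p = 0.366). Adjusted over the list alone, 1 rose and 1 fell. The CDC73 call was lost without any single array but the 15 µg/ml one, at 1.19 to 1.72, and the RTF1 call without the 40 µg/ml array, at -0.97, and 4 other single arrays.

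The ribosome lists also moved apart. Of 58 strains of the mitochondrial ribosome, 30 rose and 1 fell (37 and 1 with p adjusted over the list alone), with a median of 1.49 (camera adjusted p = 3.08e-09, and adjusted p = 0.291 with an estimated correlation). MRPS18, MRPS9, MRPL9 and MRPL24 rose by 2.99 ± 0.51, 2.84 ± 0.37, 2.56 ± 0.39 and 2.14 ± 0.29. The rise of the list was not steady, with a median of 1.07 at 5 µg/ml, 0.11 at 15 µg/ml and 1.60 at 40 µg/ml. Of 41 strains lacking 1 gene for a cytosolic large-subunit protein, 32 fell and none rose (33 and 0 with p adjusted over the list alone), with a median of -2.26 (camera adjusted p = 5.11e-18, and adjusted p = 0.0558 with an estimated correlation). RPL2B, RPL20B, RPL37A and RPL19A fell, with changes of -5.76 ± 0.55, -4.90 ± 0.64, -4.12 ± 0.45 and -3.90 ± 0.48. The 2 sections differed for RPL20B, at -7.34 and -2.46. On ratios as deposited the median was -2.02 for this list and 1.73 for the mitochondrial one.

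**Figure D3:**
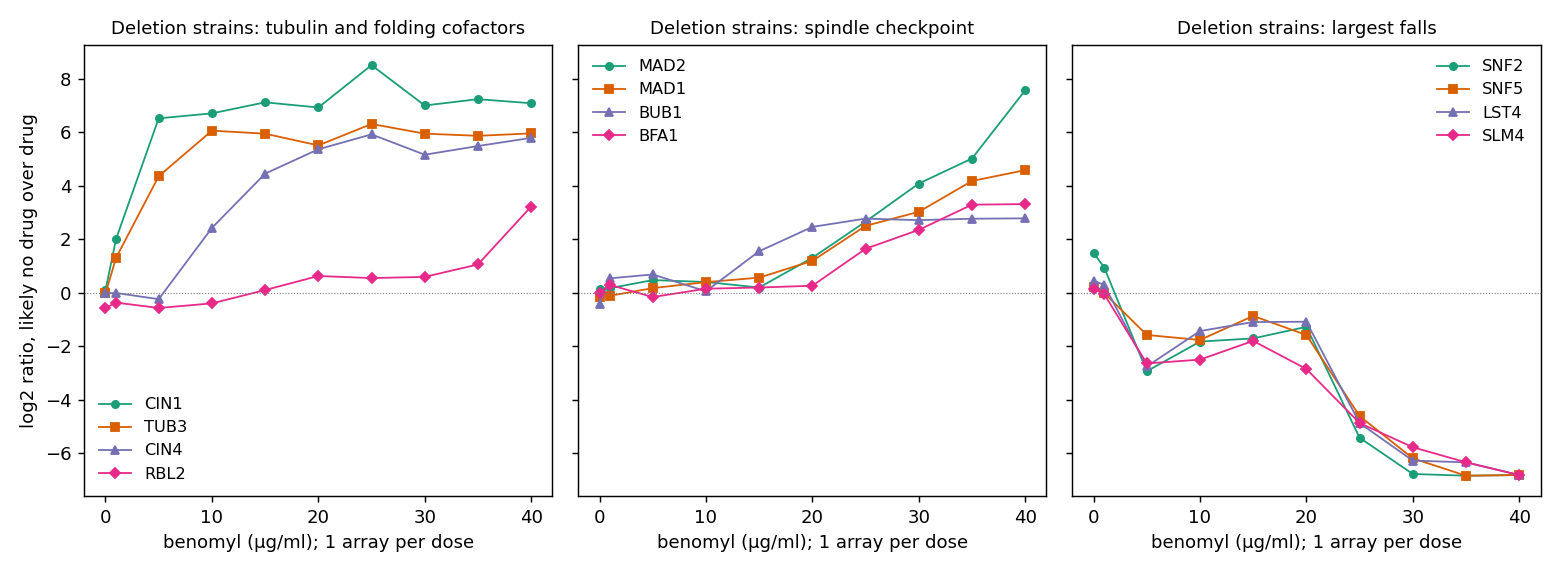
Points give the log2 ratio of single deletion strains against benomyl in µg/ml, with 1 array per dose and no error bars. CIN1 and TUB3 lie above 4 from 5 µg/ml, MAD2 and MAD1 go from 1.31 and 1.20 at 20 µg/ml to 7.57 and 4.59 at 40 µg/ml, and SNF2, SNF5, LST4 and SLM4 end at the floor of the measure, near -6.8.

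The other lists were not called, at camera adjusted p of 0.270 to 0.993. Among drug efflux genes the transporter SNQ2 alone rose, by 4.11 ± 0.70, and the transporter PDR5 was at -0.85 ± 0.29, with 1 of 11 called over the list alone as well. Among 17 vacuolar ATPase strains 3 rose and 2 fell, both over all strains and adjusted over the list alone. VMA1 and VMA8 rose by 4.22 ± 1.16 and 3.81 ± 0.89 after values of -3.10 and -2.86 at 5 µg/ml, with ratios of 2.07 and 2.16 at 40 µg/ml, and VMA11 and VMA21 fell, with changes of -1.72 ± 0.44 and -1.43 ± 0.27. The median of this list was 0.10 while its test pointed down (adjusted p = 0.993). In late ergosterol synthesis ERG2 rose by 1.07 ± 0.34 and ERG24 fell by 1.22 ± 0.36, with the same counts adjusted over the list alone. None of 8 tryptophan and aromatic amino acid strains passed, over all strains or adjusted over the list alone, and TRP2 had a change of -1.20 ± 0.51, with its sections at -3.54 and 1.15. In recombinational repair MEC3, of the damage checkpoint clamp, rose by 2.82 ± 0.48 and RAD52 fell by 1.12 ± 0.31, and adjusted over the list alone 1 rose and 1 fell. In the actin list BEM2 and END3 rose by 3.29 ± 0.55 and 1.74 ± 0.46 and ABP1 and CAP1 fell, with changes of -1.75 ± 0.31 and -1.14 ± 0.25, in all 3 rises and 4 falls of 16 (3 and 5 with p adjusted over the list alone). In the list of histidine, arginine, leucine and lysine synthesis, LEU4, ARG7, ARG1 and HIS7 fell, with changes of -6.85, -2.94, -1.45 and -1.36, of 6 falls among 22, and the list median was -0.02. Adjusted over the list alone, 2 rose and 6 fell. Without the 40 µg/ml array the calls of VMA1, END3, ERG2, ERG24, RAD52, ARG7, ARG1 and HIS7 were lost, at 4.72, 1.52, 0.92, -1.16, -0.88, -1.89, -1.06 and -0.72, and without the 1 µg/ml array that of VMA11, at -1.34. Each of these 9 calls was also lost without at least 1 other array, that of ERG2 without 7 in all and that of ERG24 without 6.

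Of the 81 background genes whose haploid deletion does not grow, RPB5, SCL1 and PUP2 fell, with changes of -2.88 ± 0.72, -2.27 ± 0.72 and -1.49 ± 0.48, and none rose. None passed with p adjusted over the list alone. The list median was -0.13. Without the 40 µg/ml array all 3 calls were lost, at -1.83, -1.81 and -1.56, and those of SCL1 and PUP2 were lost without 7 and 8 of the single arrays in all. This list was called down with days as a covariate, at -0.97 (camera adjusted p = 0.00295), and on the 4-day arrays only, at -0.86 (camera adjusted p = 0.00407), so under these fits the background itself moved.

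The dose at which strains first departed was described next. A strain was taken to respond from a given dose if it stayed at least 2-fold above the median from there to 40 µg/ml. CIN1, TUB3, PAC10, PFD1, GIM5 and CTK3, a subunit of an RNA polymerase II kinase, did so from 1 µg/ml. Another 45 strains did so from 5 µg/ml, among them CIN2, GIM3, GIM4, YKE2, SGO1, WHI2, NFU1 and MEC3. Many others of these 45 lacked mitochondrial genes, such as ACO1, ATP5, ATP7, FZO1, SDH3 and SOD2. An early onset was thus not particular to tubulin and prefoldin genes. Counts for onsets at 10, 15, 20 and 25 µg/ml were 15, 16, 73 and 162, and MAD1, MAD2, IRA1 and NPR3 were among those from 20 µg/ml. For onsets at 30, 35 and 40 µg/ml the counts were 54, 168 and 487, the last resting on the 40 µg/ml array alone. The lists overlapped, since CIN4, ALF1 and RBL2 of the tubulin list did so from 10, 20 and 35 µg/ml, and of the spindle checkpoint list BUB1 and BUB3 did so from 15 µg/ml. By the same rule below the median, 5 strains responded from 1 µg/ml, 106 from 5 µg/ml, 146 from 25 µg/ml and 432 at 40 µg/ml only. This description carries no test, and CTK3 and the mitochondrial genes from ACO1 to SOD2 were chosen after their values were seen.

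The second comparison set the 5 arrays of 4 days (20 to 40 µg/ml) against the 4 arrays of 2 days (0 to 10 µg/ml), so days and dose cannot be told apart in it. Among strains past the threshold the largest differences were of CIN4 and UBI4, at 5.00 and 4.74 (limma adjusted p = 0.00394 and 0.0123). CIN4 had a mean of 5.55 ± 0.31 (SD, n = 5) on the 4-day arrays and 0.54 ± 1.26 (SD, n = 4) on the 2-day arrays. UBI4 was at 4.35 ± 1.18 and -0.38 ± 0.83, and BUB1 at 2.70 ± 0.14 and 0.22 ± 0.50. In limma 46 strains were higher and 14 lower on the 4-day arrays, and 44 and 14 of these were also called in the dose trend in the same direction. The strains called here and not in the dose trend were SKN7, a regulator of the oxidative and osmotic stress response, with a difference of 2.65, and GUK1, guanylate kinase, which is needed for growth, with 0.94. Both of those calls were lost without most single arrays, for example at 2.61 and 0.90 without the no-drug array. The counts rested on single arrays. They were 279 and 216 without the 20 µg/ml array, 12 and 0 without the no-drug array, 4 and 0 without the 1 µg/ml array, and 7 and 1, 5 and 0, 13 and 0, and 9 and 0 without the 25, 30, 35 and 40 µg/ml arrays. With arrays scaled to equal spread they were 20 and 2.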

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

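The tests of other orders of the doses, of the ribosomal protein strains, of the likeness of the 25 to 40 µg/ml arrays and of the agreement of tags for TIM12 and NUP57 were chosen after the results were seen, while the count of other splits of the days and the look at chromosomal neighbours were written down before, the latter for TIM12 and NUP57 together.

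The slope against dose differed between the 4-day and the 2-day arrays in 10 strains, 5 with a higher and 5 with a lower slope at high dose (limma, interaction of dose and days). PFD1, of prefoldin, had a slope of 6.04 per 10 µg/ml on the 2-day arrays and -0.44 on the 4-day arrays, a difference of -6.48 (limma adjusted p = 0.0121). TUB3 had 5.95 and 0.09, a difference of -5.86 (limma adjusted p = 0.0360). Spots that the annotation does not name also carried signal, since 46.0% of them were at least 2-fold off the median at 40 µg/ml, against 10.8% without drug and against 46.2% of named spots at 40 µg/ml. Of 1239 unnamed spots tested, 104 rose and 118 fell with dose, with spots 1160 and 3106 at 4.73 and 4.62 and spots 1335 and 1336 at -6.98 and -6.63 (limma adjusted p = 0.0107, 0.00350, 0.0126 and 0.0149).

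A chance order of the doses is argued against for the number of dose-trend calls, though days of selection also rise with dose in the real order. Among 100 orders of the 10 doses, 1, the real one, gave as many as 1033 calls, and the next highest gave 695. Of the other 99 orders, 4 gave any call. For the second comparison, 4 of 100 splits of the 9 arrays gave as many as the real 60 calls, the real one included. Chance is not excluded by this count, because the arrays differ in dose and the splits with more calls followed another grouping of them. The highest other split gave 591 calls and set 25, 30, 35 and 40 µg/ml against 0, 1, 5, 10 and 20 µg/ml, and the 2 splits after it, with 249 and 72 calls, also kept the 25 to 40 µg/ml arrays together. That points to a structure of the arrays in which those from 25 to 40 µg/ml go together.

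The first pattern is this likeness, since arrays from 25 to 40 µg/ml correlated with each other at 0.74 to 0.85 across strains, those from 5 to 20 µg/ml at 0.56 to 0.75, and arrays of these 2 ranges with each other at 0.45 to 0.62, which overlaps with the 5 to 20 µg/ml values. Days of selection as the cause stay open. The 4-day array at 20 µg/ml correlated better with the 3-day array at 15 µg/ml (0.75) than with the 4-day array at 25 µg/ml (0.62), a difference of 0.124. The covariances went the other way, at 0.39 and 0.46, and the comparison rests on 1 array, that at 20 µg/ml. A batch of arrays or of no-drug pool shared by the 25 to 40 µg/ml arrays cannot be told apart from dose, because no label gives a batch and each dose has 1 array. The no-drug array correlated with the 25 to 40 µg/ml arrays by 0.0632 more than with the 5 to 20 µg/ml arrays. It was selected for 2 days, so it cannot hold a 4-day no-drug pool that those arrays may share. Simulated arrays with no effect that share 1 control pool gave a correlation of 0.50 and a covariance of 0.13. Those 2 values follow from the equal noise put in, taken from the no-drug array, so they decide nothing about a batch. The observed covariance between 35 and 40 µg/ml was 1.54. The spread across strains did not grow steadily with dose. Its standard deviation was 0.89, 0.86, 0.72 and 0.73 at 5, 10, 15 and 20 µg/ml, then 1.01 at 25 µg/ml and 1.46 at 40 µg/ml. The lower spread at 15 and 20 µg/ml came with 3 and 4 days of selection in place of 2. A graded change with dose and a dose threshold between 20 and 25 µg/ml both stay open. Neither was tested apart from days of selection or from batch.

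The second pattern is the fall of strains lacking a cytosolic large-subunit ribosomal protein, with a median of -2.26. The centring done here is argued against as the cause. It took off array medians of only -0.0801 to 0.189, and the list median was -2.02 (SEM 0.28, n = 41 strains) on ratios as deposited. Whether the authors had normalised the ratios before is not known. Each SEM here is over strains read on the same arrays, not over replicates. A gain of every slow-growing class alike was looked at through mitochondrial ribosome strains, which had a median of 1.49 (SEM 0.15, n = 58 strains), the other way. The 2 ribosome lists thus did not move alike. An effect of slow growth on the large-subunit strains stays open, because no growth rate was measured here. Longer selection with no effect of dose is argued against, because the median change from 20 to 40 µg/ml within the 4-day arrays was -2.03 (SEM 0.20). The background list also went down there, by less, from a median ratio of 0.02 at 20 µg/ml to -0.54 at 40 µg/ml. An effect of the drug specific to these strains stays open and no mechanism was tested, since the pattern was found and looked at on the same data and its call is not past the threshold with an estimated correlation (adjusted p = 0.0558).

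The third pattern is the fall of strains whose gene is needed for growth, TIM12 (-7.32) and NUP57, a nuclear pore gene chosen after its values were seen (-5.38). For NUP57, which stayed above the floor, both sections of the layout fell, at -5.91 and -4.86, a difference of 1.05 in the fitted change. NUP57 was picked after its large mean fall was seen, which makes such agreement likely, so a fault of 1 tag is not excluded. For TIM12 it stays open too, since a strain picked for its large mean fall and read at the floor on 2 arrays must agree between sections (a difference of 0.0476). For TIM12 a signal from a deleted neighbour is argued against, since its neighbours YBR090C and PHO3 had changes of 0.20 and 0.14. For NUP57 it stays open, since its neighbour RPS23A, a ribosomal protein gene, fell by 2.84, less than NUP57 itself. A strain with a tag recorded under the wrong gene, or with a second copy of the gene, was not tested, and no biological explanation was tested.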

How the results depend on the processing

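The fits on 1 section of the layout, on strains whose sections agree and with coded values kept, and the lists after quantile normalization, were chosen after the data were seen, and the others before. No paired analysis was possible because each dose has 1 array and the groups share fewer than 2 replicate numbers. Fits on uptags or downtags alone were not run, since tags are not marked. The cause of each change below was not tested unless given.

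Over 29 alternatives, the 88 named strains called in the dose trend gave 2526 values, of which 1976 kept direction and call, 525 kept direction only and 25 reversed. The 10 called lists gave 230 values, of which 211 kept direction and call, 15 direction only and 4 reversed, where a list counts as reversed if its set test or its median turned. None of these strains or lists reversed without centring, with equal spread or after quantile normalization, though 9, 70 and 44 of the strains lost the call. With days as a covariate 53 of the 88 strains lost the call and 2 reversed, on the 4-day arrays only 55 and 4, on the 2-day arrays only 70 and 18, and with log2(dose + 1) 39 lost it. Leaving out single arrays ended the call of 31 named strains at adjusted p of 0.0506 to 0.237 (limma), most often without the 40 (25), 35 (23), 1 (15) or no-drug (13) array, and ended no call of a list. Some alternatives could hardly differ from the main fit. Values on at least 5 arrays kept the same 5325 strains, and values on all arrays kept 5322. Treated arrays only is the same fit as that without the no-drug array. Strains whose sections agree were chosen for that agreement. The tallies thus overstate how stable the calls were.

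The main counts of strains that rose and fell with dose were 547 and 486. Without median centring 851 rose. Arrays scaled to equal spread gave 41 and 24, quantile normalization 107 and 133, log2(dose + 1) 232 and 260, days as a covariate 157 and 182, and the 4-day arrays only 93 and 157. The 2-day arrays only gave 0 and 0 in limma, with 199 and 320 at an unadjusted p below the threshold and a lowest adjusted p of 0.316, from only 4 arrays. Leaving out each array gave 314 to 614 that rose and 308 to 545 that fell, lowest without 40 µg/ml and highest without 5 µg/ml, and 321 fell without 1 µg/ml.

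For 4-day against 2-day arrays (46 higher and 14 lower), equal spread gave 20 and 2, quantile normalization 17 and 7, treated arrays only 12 and 0, array weights 92 and 42, the first section 21 and 3, and the second section 6 and 0, while robust eBayes gave 6 lower. Leaving out each array gave 4 to 279 higher and 0 to 216 lower, the highest without 20 µg/ml and the lowest without 1 µg/ml.

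For strains at least 2-fold above and below the median (129 and 204 at 0, 1026 and 966 at 40 µg/ml), equal spread gave 408 and 667 at 0 and 337 and 351 at 40 µg/ml. At 0 the first section gave 217 and 422, the second 229 and 366, and strains whose sections differ by under 1 gave 38 and 94, with 636 below at 40 µg/ml. A threshold of 1.5-fold gave 343 and 579 at 0 and 1622 and 1517 at 40 µg/ml, and 4-fold gave 12 and 27, and 327 and 343.

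Of the lists (6 up and 4 down), an estimated correlation left 2 up and 1 down. Days as a covariate gave 8 down, the 4-day arrays only 7 down and the 2-day arrays only 3 up. The tubulin and prefoldin lists lost the call with days as a covariate, at 2.58 and 3.44 (adjusted p = 0.578 and 0.181), the prefoldin list with equal spread, at 1.26 (adjusted p = 0.425), and the dynein list with log2(dose + 1), at -0.75 (adjusted p = 0.0787). Lists newly called down with days as a covariate and on the 4-day arrays were the background genes whose haploid deletion does not grow, at -0.97 and -0.86 (adjusted p = 0.00295 and 0.00407), the PAF1 list, at -3.20 and -2.74 (adjusted p = 0.00255 and 0.00407), and the actin list, at -2.48 and -2.14 (adjusted p = 0.000774 and 0.0233), and with the covariate the vacuolar ATPase list, at -1.24 (adjusted p = 0.0285). On the 2-day arrays only, the tubulin, SWR1, Rpd3 and SAGA lists lost the call, at 9.30, 0.71, -2.56 and -1.88 (adjusted p = 0.113, 0.432, 0.113 and 0.113), and the CTF19 and dynein lists, which reversed, were not called either (adjusted p = 0.876 and 0.154). There the vacuolar ATPase and actin lists were newly called down, at -7.14 and -3.25 (adjusted p = 2.57e-06 and 0.000247).

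Reversals came from the fit with days as a covariate, from subsets of doses and from 1 section. With days as a covariate ALF1 was at -2.28 and VMA1 at -0.19. On the 4-day arrays only, CIN1 was at -0.76, ALF1 at -0.62, GIM4 at -1.34, CIK1 at 0.96, the prefoldin list at -0.30 and the tubulin list at -0.29, although the set test of the latter still pointed up. On the 2-day arrays only, with the slope scaled to 40 µg/ml, UBI4 was at -1.80, DHH1 at -0.27, ALF1 at -9.34, BFA1 at -0.096, MCM16 at -0.18, CTF18 at -2.69, VMA8 at -7.18, VMA1 at -8.89, SNQ2 at -3.36, CDC73 at -3.16, BEM2 at -1.77 and END3 at -3.27. There ARP1 was at 1.98, DYN2 at 1.35, DYN3 at 2.57, SGF73 at 0.33, ARG1 at 0.77, HIS7 at 0.60, the CTF19 list at 0.19 and the dynein list at 0.95. On the second section BUB2 was at -0.12. Signal over background is not given in the value table used here, so its effect on these calls is unknown.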

Other observations

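The 8 groups in this part, and the test on them, were chosen after the strains that moved had been seen, so their counts are descriptions, while the test of chromosomal neighbours was written down before. Strains that lack activators of the nutrient kinase TORC1 had falling ratios: 8 of 10 genes of the EGO complex, SEACAT and the Lst4-Lst7 pair fell, with a median of -6.30, among them GTR1 at -6.56, GTR2 at -5.99, MEH1 at -6.17 and RTC1 at -6.43. Both measured genes of SEACIT, which inhibits TORC1, rose, NPR3 by 5.43 and NPR2 by 3.21. In a group taken as negative regulators of the Ras and protein kinase A pathway 9 of 10 rose, with a median of 3.29, including IRA1, IRA2 at 3.92, GPB1 at 4.38 and PDE2 at 2.27. The group is broad, since it also holds RIM15 (4.58), a kinase that the pathway inhibits, and the stress response genes WHI2, PSR1 and PSR2. GPB2, at 2.04, had its sections at 4.85 and -0.76. Of 10 SWI/SNF genes 7 fell, with a median of -4.61.

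Members of metabolic groups were also among the strains called. Of 24 genes of peroxisome biogenesis 11 fell, such as PEX10 at -5.70, PEX8 at -5.51 and PEX5 at -5.11, and 3 rose, which were PEX29, PEX30 and PEX27 at 1.91, 1.17 and 0.96. The falls of PEX10, PEX8 and PEX5 were not steady. Their ratios were -3.56, -3.42 and -3.27 at 5 µg/ml, 0.59, 0.30 and 0.59 at 20 µg/ml, and -4.37, -3.96 and -3.67 at 25 µg/ml. Of 8 genes of the GID ubiquitin ligase, which degrades gluconeogenic enzymes, 5 fell, among them VID28 at -4.22 and UBC8 at -3.89. VID28 took a like course, at -3.5, 0.16 and -3.28 at 5, 20 and 25 µg/ml. Of 6 genes of mitochondrial retrograde signalling, RTG1, RTG2 and BMH1 rose by 4.10, 3.61 and 2.35, MKS1 fell by 5.68, and RTG3 at 2.17 and LST8 at -0.93 did not pass, and this group was not called (camera adjusted p = 0.104). Of 46 cytosolic small-subunit ribosomal protein genes 24 fell and none rose, with a median of -1.55, close in kind to the large-subunit list fixed beforehand. With an estimated correlation 0 of the 8 groups passed (camera adjusted p = 0.0566 to 0.308), so whether they moved more than other strains stays open.

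Deletion of a gene may also affect its chromosomal neighbour. To keep spots of a pair apart, the change of each gene in 1 section of the layout was set against that of its neighbour in the other. Over 4869 neighbouring pairs the mean correlation was 0.0281, above the 95th percentile of 0.0194 in 10000 shuffled gene orders (permutation p = 0.0081, one-sided), and the same strain in both sections gave 0.62. The relation is thus small and across genes, which are not independent replicates. Both partners were above 3 in 3 pairs, against 1.52 on average after shuffling, and below -3 in 6 pairs, against 3.24, neither beyond the highest shuffled counts of 6 and 10. PSO2 (6.11), a DNA repair gene among the largest rises, lies next to CIN4 (6.62), of the tubulin folding pathway, although PSO2 was at 0.56 at 20 µg/ml, where CIN4 was at 5.37. PBA1 lies next to YKE2 of prefoldin in the same way. Whether these are effects on the neighbour was not tested for single pairs.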
